A study of Arabidopsis thaliana with 15 samples.

How the data were processed

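The samples were 14-day-old Arabidopsis seedlings. Per the labels' protocols they were grown on plates in long days, and total RNA was taken from frozen whole seedlings. The 15 libraries fall into 8 groups by their titles: RNA-seq of WT (3) and of syd-5 (3), ChIP with an antibody against GFP from a syd-5 line with a GFP-tagged SYD (2, with 1 input), and H3K27me3 ChIP from WT (2, with 1 input) and from syd-5 (2, with 1 input). The 9 ChIP and input libraries were not analysed here. The labels do not say whether libraries of one group came from separately grown plants, and the sources do not say how the authors' p-values treat the libraries, so that any spread between libraries behind them may be technical.

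The only table used holds the authors' comparison of syd-5 with WT RNA. It has 1 value per gene and genotype, a test statistic, a p-value and a q-value. Bowtie2, TopHat2 (version 2.0.4), bedtools and the genome build TAIR10 are named in the submitters' processing notes, which give no role for each. The program that made the table is not given in the sources used here, and its columns have the layout of a Cuffdiff gene comparison. The authors' expression values were read as FPKM, which the file header does not state. They are not whole, their sums differ between the genotypes, and their log2 ratio equals the deposited fold change for every tested gene with a finite ratio. The test statistic is the authors' score and was not used. The p-value and q-value are the authors', as deposited, and the q-values equal a Benjamini-Hochberg adjustment over the 19868 tested genes (largest difference 5.22e-07). The deposited log2 column was not used, because 1038 of its cells, all with syd-5 at 0, hold a spreadsheet error in place of a number and 580 hold infinity. The columns name only the genotypes and give no value per library. No library's depth, no standard deviation and no interval can therefore be given, and the precision of single values is unknown. Values at exactly 0 are described as listed at 0, with no fold.

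The designs fixed before the data were examined foresaw counts or values per library. As the table gives neither, the planned fallback was used: q of at most 0.05 in the authors' deposited table was taken as given and no test was made on single genes. Fold changes are log2 of FPKM in syd-5 over FPKM in WT, with no pseudocount. Gene symbols came from a RefSeq gene table (assembly TAIR10.1), in which 32208 of the 33201 IDs (97.0%) matched. It was used for names, gene classes and neighbour order only. Coordinates are those of the authors' table, counted from 1. Of the listed genes 3870 have a span that overlapping genes share (3172 tested, 622 called), and their values are treated as less certain, as are those of near-identical paralogs. The table has 286 entries that join several gene IDs. The SWI/SNF member BRIP1 occurs only in such an entry and was left out. All 271 organellar genes are listed at 0.

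The text names SYD and BRM, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 FPKM over the genotypes, and up to 4 called members of each list with the smallest q, a rule fixed before the data were examined. Ties in q were broken by the larger fold change. Genes listed at 0 in one genotype cannot be ranked by fold and are given apart. Other list members named in the text were chosen after their values were seen.

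The 21 gene lists (342 members) were fixed before the data were examined: SWI/SNF subunits, Polycomb and its antagonists, floral homeotic and meristem genes, seed maturation, flowering time, jasmonate, ethylene and jasmonate defence, salicylic acid defence, auxin, gibberellin, abscisic acid and cold, photosynthesis, anthocyanin and flavonoid, glucosinolate, leaf polarity, circadian clock, heat shock, touch and rapid stress, reference genes, and markers of root cells and of trichomes and epidermis. For each, the called share of tested members was compared with all other tested genes by a two-sided Fisher's exact test, adjusted over the 21 lists by Benjamini-Hochberg. The median log2 fold change was placed among 10000 random lists of equal size drawn from 20 bins of mean FPKM. Counts adjusted over the list alone used the authors' p-values of its tested members. On simulated data with 19868 genes and lists of 15, for the comparison of syd-5 with WT, the percentile recovered 20 of 20 lists shifted by 1 on the log2 scale. The Fisher test was checked on calls drawn at random, apart from the fold changes. It recovered 14 of 20 lists given a raised share of calls, so that these 2 rates do not compare. Of the 20 unchanged lists 0 were found by either. The simulated lists were drawn at random from shuffled values, so that they held no genes that change together. How often lists of related genes or close copies pass falsely is therefore unknown. Position was tested by a two-sided Fisher's exact test within 5 Mb of SYD and per chromosome, the latter adjusted over 5.

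Alternatives were a threshold of 0.01, a fold of at least 2, a mean of at least 1 FPKM with the adjustment recomputed, an adjustment over every gene with a p-value, centring on the median, and windows of 2 and 10 Mb. Chosen after the data were seen were a fold of at least 2 on log2(FPKM + 1), a mean of at least 10 FPKM, and leaving out genes with shared spans. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.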

Results

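The series profiled 14-day-old Arabidopsis thaliana seedlings with 15 libraries. RNA-seq covered wild type Col-0 (WT, 3 libraries) and syd-5 (3 libraries), a mutant of SPLAYED (SYD), which encodes an ATPase of SWI/SNF chromatin remodelling complexes and is a close homolog of BRAHMA (BRM). The other 9 libraries were chromatin immunoprecipitations and their inputs and were not analysed here. They covered a GFP-tagged SYD (2 libraries and 1 input) and the Polycomb mark H3K27me3 in WT (2 libraries and 1 input) and in syd-5 (2 libraries and 1 input). Expression values came from the authors' comparison of syd-5 with WT, which gives 1 value per gene and genotype. These values were read as FPKM, a unit the table itself does not name. No spread between replicates and no sequencing depth stands behind any single value. The comparison listed 33201 genes, of which the authors had tested 19868. The FPKM summed to 865406 in WT and 948154 in syd-5, and 23279 and 22821 genes lay above 0. The 10 most abundant tested genes held 6.50% of the sum in WT and 6.70% in syd-5. A gene is said to have risen, fallen or been called only where q was at most 0.05 in the authors' deposited table.

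The first question was whether the mutant label and the transcripts match. SYD (AT2G28290, TAIR10 chromosome 2, 12054736 to 12073083) fell 5.17-fold in syd-5, to 2.53 FPKM from 13.1 FPKM in WT (log2 -2.37, q = 0.000351 in the authors' deposited table). Because an insertion allele can keep transcript on either side of the insertion, this value checks the label only in part, and the listed span is shared with a neighbouring pseudogene, AT2G28280. BRM (AT2G46020) stood at 21.2 FPKM in WT and 19.6 FPKM in syd-5 and was not called (log2 -0.11, q = 0.595 in the authors' deposited table). Of 21 tested genes for SWI/SNF subunits, 2 rose, 1 fell, which was SYD itself, and 18 were not called. The subunit gene SWP73A rose to 8.02 FPKM from 5.58 FPKM, and BRD1, which encodes a bromodomain subunit, rose to 19.1 FPKM from 14.7 FPKM. The called share was 14.3% against 32.1% of the other tested genes (two-sided Fisher's exact test, p = 0.196 adjusted over 21 lists). The list's median log2 fold change was 0.04 and its mean -0.02, so that these differed in sign.

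The main comparison asked which transcripts differed between syd-5 and WT seedlings. For RNA syd-5 was the only mutant line, and binding of SYD was not analysed. Direct effects of SYD can therefore not be told apart from indirect ones or from differences in growth or harvest. Of the fixed lists, 12 of 16 tested genes of abscisic acid and cold responses were lower in syd-5 and 19 of 22 tested photosynthesis genes were higher. The floral repressor FLC rose 6.34-fold, and the floral activator AGL24 fell 27.2-fold. By q in the authors' deposited table, 6380 of 19868 tested genes (32.1%) were called, of which 2806 rose and 3574 fell. Most changes were modest. The median called gene differed 1.70-fold (0.77 on the log2 scale), and the smallest called change was 0.34 on that scale. Of the 2298 called genes with at least a 2-fold difference, 654 rose and 1644 fell (71.5% lower). The lean towards lower expression depended on the expression level. Among called genes with a mean of at least 10 FPKM, 1955 rose and 1777 fell (47.6% lower), although 529 of the 820 in that set that differed at least 2-fold were lower. By class of gene, 2710 protein-coding genes rose and 3497 fell of 19044 tested. Among 165 tested lncRNA genes 10 rose and 2 fell, and among 123 tested pseudogenes 20 rose and 12 fell. The table's smallest p was 5e-05, shared by 2831 genes, so that the smallest q, 0.000351, does not rank them in the authors' deposited table.

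**Figure D1:**
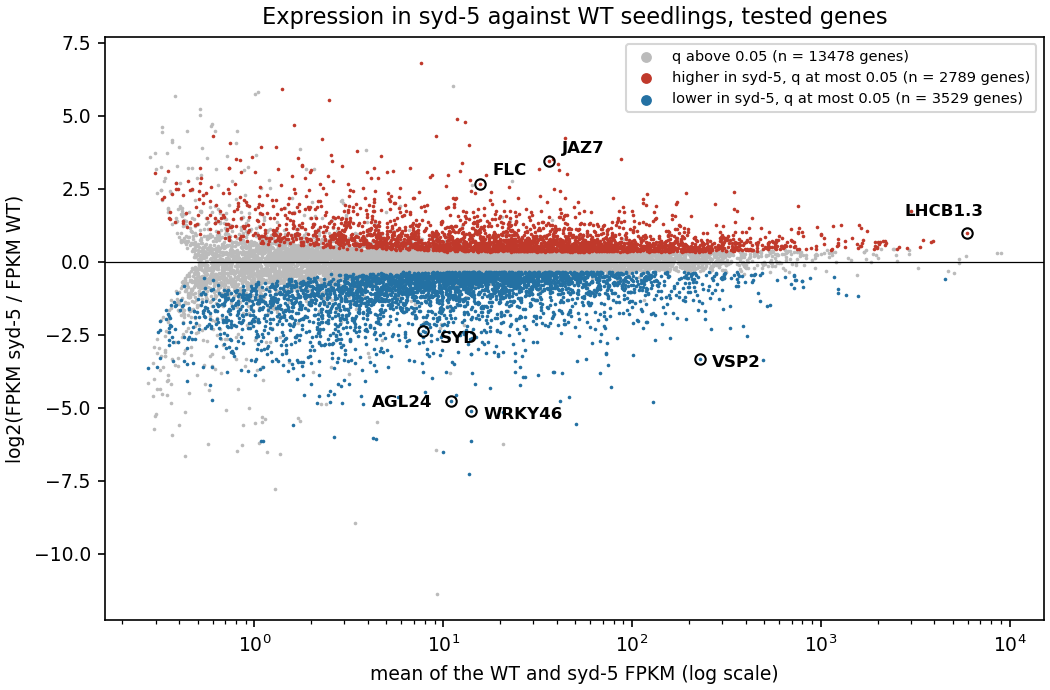
Log2 ratio of the authors' FPKM in syd-5 over WT (y axis) against the mean FPKM of the genotypes (x axis, log scale), 1 point per tested gene with a value above 0 in both (19796 genes). Red points (2789) were called higher and blue points (3529) lower in syd-5. The genes circled are SYD (log2 -2.37), FLC (2.66), JAZ7 (3.43), WRKY46 (-5.12), AGL24 (-4.77), VSP2 (-3.33) and LHCB1.3 (0.99), and the blue cloud reaches farther from 0 than the red one.

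The 12 largest falls among called genes with a mean of at least 1 FPKM spanned log2 -7.26 to -5.12. JAL23 (AT2G39330, chromosome 2, 16419596 to 16421852), a jacalin-related lectin gene, fell 153-fold, to 0.178 FPKM from 27.1 FPKM in WT. PR2 (AT3G57260), a glucanase gene used as a marker of salicylic acid defence, fell 67.4-fold to 0.129 FPKM from 8.71 FPKM. WRKY46 (AT2G46400), which encodes a transcription factor of defence and stress responses, fell 34.7-fold to 0.784 FPKM from 27.2 FPKM. QQS (AT3G30720), an orphan gene linked to starch content, fell 35.5-fold to 1.13 FPKM from 40.2 FPKM, and AT2G05510 fell 46.7-fold to 2.11 FPKM from 98.6 FPKM. The others were DIP2 (log2 -6.54), AT5G52760 (-6.16), AT1G12570 (-6.15), AT1G55440 (-6.15), AT1G80130 (-6.03), AT5G22430 (-6.02) and the cellulose synthase-like gene CSLG2 (-5.58). A syd-5 value near 0 makes such a fold imprecise, as for AT1G12570 (to 0.0308 from 2.19 FPKM) and AT1G55440 (to 0.0301 from 2.13 FPKM). DIP2, AT1G12570, AT1G55440 and AT5G22430 had q = 0.0114 in the authors' deposited table. Called genes listed at 0 in one genotype have no finite fold and were kept apart, 45 of them listed at 0 in syd-5 and 17 in WT. Those listed at 0 in syd-5 with a mean of at least 1 FPKM were LURP1, which acts in defence against oomycetes (20.8 FPKM in WT), AT5G23155 (11.5), the lipid transfer protein gene LTP4 (4.97), AT1G53610 (3.32), the metal transporter gene ZIP7 (3.31), AT3G11773 (2.76) and AT5G19800 (2.13).

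The 12 largest rises spanned log2 3.91 to 6.79. AT4G25580 (chromosome 4, 13056184 to 13058802) rose 111-fold, to 15.1 FPKM from 0.136 FPKM in WT. AT3G28220 reached the highest level of the 12, at 83.8 FPKM against 4.47 FPKM (18.8-fold). AT1G50040 rose to 25.1 FPKM from 0.922 FPKM and AT1G52270 to 25.9 FPKM from 1.63 FPKM. The pseudogene AT5G35935 rose by log2 5.92, AT1G78720 by 5.54, AT3G43850 by 4.87, AT4G32510 by 4.68 and AT3G61920 by 4.31. The serine carboxypeptidase-like gene scpl17 rose by log2 4.19. BSU1, which encodes a phosphatase of brassinosteroid signalling, and ABCE1 each rose by log2 3.91. Of the 17 called genes listed at 0 in WT, those with a mean of at least 1 FPKM were AT2G16367 (5.17 FPKM in syd-5), the peroxiredoxin gene PER1 (2.34) and AT5G67411 (2.06).

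Several activators of flowering were lower in syd-5, and the repressor FLC was higher. FLC (AT5G10140, chromosome 5, 3173497 to 3179448), which delays flowering until vernalization, rose 6.34-fold, to 27.05 FPKM from 4.27 FPKM. The floral activator AGL24 (AT4G24540) fell 27.2-fold to 0.780 FPKM from 21.2 FPKM, and SOC1 (AT2G45660), which integrates flowering signals, fell to 9.69 FPKM from 38.8 FPKM. SPL3 (AT2G33810), which promotes the floral transition, fell 8.13-fold to 2.16 FPKM from 17.58 FPKM, with a span shared with another gene. Transcripts of FT, the mobile flowering signal, fell to 1.62 FPKM from 4.11 FPKM. Of 21 tested members 4 rose (FLC, MAF4, SMZ and SNZ, all repressors), 10 fell and 7 were not called, and adjusted over the list alone 5 rose and 10 fell. The members that fell also included FD, SPL4, SPL9 and the repressors TFL1, TEM1 and MAF5. The call of TFL1 was lost when the adjustment included the untested genes (q = 0.0581 from the p-values of the authors' deposited table). No change was called for SVP (97.7 and 83.7 FPKM) or CO (2.88 and 4.17 FPKM, q = 0.0578 in the authors' deposited table). The called share was 66.7% (two-sided Fisher's exact test, p = 0.00786 adjusted over 21 lists). The median log2 fold change of -0.46 lay at percentile 0.07 of 10000 random lists of equal size and matched expression. Genes are not independent replicates, so that the list tests describe these values only. MAF4 and MAF5 are close copies in a gene cluster, and their values are less certain.

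**Figure D2:**
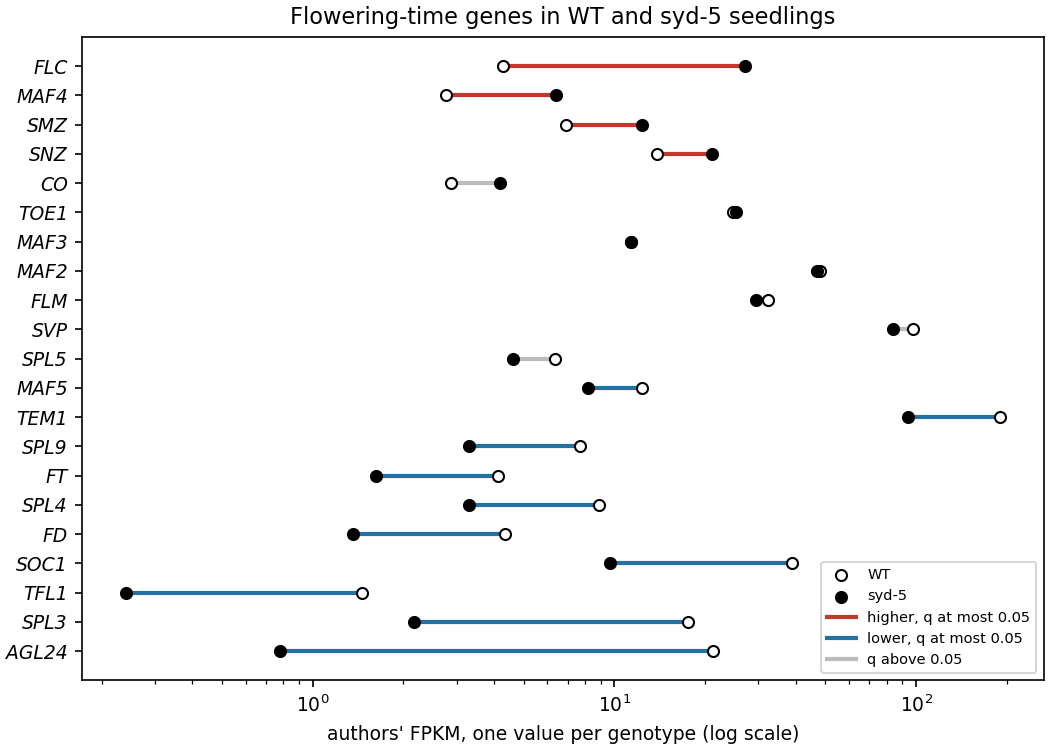
The authors' FPKM of the 21 tested flowering-time genes (x axis, log scale, 1 value per genotype, no replicate error) in WT (open circles) and syd-5 (filled circles), ordered by log2 ratio. Red lines join genes called higher in syd-5, with FLC at 4.27 and 27.05 FPKM, blue lines genes called lower, with AGL24 at 21.2 and 0.780 FPKM, and grey lines genes not called.

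Floral organ and meristem genes went both ways. AP1, which specifies the floral meristem, was at 1.28 FPKM in WT and listed at 0 in syd-5. FUL, an activator of the transition to inflorescence, fell 7.93-fold to 0.969 FPKM from 7.68 FPKM, and the shoot meristem gene STM fell 1.85-fold to 3.31 FPKM from 6.13 FPKM. In contrast, SEP3 rose 2.38-fold to 53.3 FPKM from 22.3 FPKM, PI rose 3.76-fold to 6.74 FPKM from 1.79 FPKM, and SEP4 rose 2.21-fold. Of 18 tested members 3 rose, 7 fell (AP1, FUL, SEP1, CUC3, SHP1, AP3 and STM) and 8 were not called, and adjusted over the list alone 4 rose and 8 fell. The called share of 55.6% did not pass the test (two-sided Fisher's exact test, p = 0.120 adjusted over 21 lists), while the median of -0.74 lay at percentile 1.34 of matched random lists. SEP1 and SHP1 share their spans with other genes. The calls of SHP1 and CUC3 were lost when the adjustment included the untested genes (q = 0.0614 and 0.0665 from the p-values of the authors' deposited table).

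Defence genes of the salicylic acid pathway were lower in syd-5 wherever they were called. WRKY70 fell 11.5-fold to 11.9 FPKM from 137 FPKM, and CBP60G and SARD1, which encode activators of salicylic acid synthesis, fell 5.77-fold (to 6.57 from 37.9 FPKM) and 3.81-fold (to 3.83 from 14.6 FPKM). PR1, the standard marker of the pathway, was at 1.56 FPKM in WT and listed at 0 in syd-5. Of 16 tested members 8 fell, none rose and 8 were not called, among these the biosynthesis gene ICS1 (3.48 and 3.1 FPKM) and the receptor gene NPR1 (23.9 and 20.4 FPKM). PR5, another PR gene of the list, was not called either, at 15.9 FPKM in WT and 16.3 FPKM in syd-5 (q = 0.914 in the authors' deposited table). The called share of 50.0% did not pass the test (two-sided Fisher's exact test, p = 0.248 adjusted over 21 lists), but the median of -1.40 lay below all 10000 matched random lists. In the ethylene and jasmonate defence list 4 of 8 tested members fell, 1 rose and 3 were not called. ERF1 fell 13.2-fold to 0.526 FPKM from 6.95 FPKM and the chitinase gene PR3, whose span is shared, fell 4.40-fold to 11.5 FPKM from 50.5 FPKM, whereas ORA59, a transcription factor gene of the same branch, rose 2.33-fold to 31.3 FPKM from 13.4 FPKM. PR4 fell to 115 FPKM from 268 FPKM. PDF1.2A, the other member that fell (log2 -4.62), has near-identical copies and is uncertain. The median of this list, -1.72, also lay below all matched random lists, and its called share of 62.5% did not pass (two-sided Fisher's exact test, p = 0.196 adjusted over 21 lists).

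Jasmonate genes split into risers and fallers. JAZ7, a repressor of jasmonate signalling, rose 10.8-fold to 66.9 FPKM from 6.19 FPKM, and JAZ6 rose 2.56-fold to 164 FPKM from 63.9 FPKM. The jasmonate marker VSP2 fell to 41.5 FPKM from 416 FPKM, VSP1 fell 19.8-fold to 7.42 FPKM from 147 FPKM, and TAT3 fell 7.07-fold to 0.641 FPKM from 4.53 FPKM. VSP1 and VSP2 are near-identical, so that their reads can be split wrongly between them. MYC2, the main activator of the response, fell 2.11-fold to 46.3 FPKM. Of 23 tested members 8 rose, 8 fell and 7 were not called, and adjusted over the list alone 9 rose and 8 fell. The called share was 69.6% (two-sided Fisher's exact test, p = 0.00272 adjusted over 21 lists), with a median of -0.10 at percentile 9.46.

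Genes of abscisic acid and cold responses were lower in syd-5. NCED3, which encodes a rate-limiting enzyme of abscisic acid synthesis, fell 10.8-fold to 0.694 FPKM from 7.52 FPKM. The stress marker RD29A fell to 4.76 FPKM from 21.9 FPKM, and the cold-response gene COR15A fell 4.04-fold to 17.36 FPKM from 70.1 FPKM. The phosphatase genes ABI1, ABI2 and HAB1, negative regulators of the pathway, fell too, by log2 changes of -1.04, -1.38 and -1.61. RD29B, the neighbour of RD29A, was the 1 member that rose, to 3.11 FPKM from 0.842 FPKM. Of 16 tested members 1 rose, 12 fell and 3 were not called (81.3% called, two-sided Fisher's exact test, p = 0.000782 adjusted over 21 lists), and the median of -1.32 lay below all matched random lists. COR15A and COR15B, and KIN1 and KIN2, are close copies and less certain.

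Of the rapid stress and touch genes, 5 of 7 fell. ZAT10 and ZAT12, which encode zinc finger proteins of abiotic stress responses, fell 6.16-fold (to 44.2 from 272 FPKM) and 3.44-fold (to 25.8 from 88.7 FPKM). WRKY40 fell 6.44-fold to 35.4 FPKM from 228 FPKM and WRKY33 fell 3.23-fold to 116 FPKM from 374 FPKM, both with shared spans. TCH4, an enzyme gene of the cell wall, rose to 460 FPKM from 312 FPKM. Of 7 tested members 1 rose, 5 fell and 1 was not called (two-sided Fisher's exact test, p = 0.0233 adjusted over 21 lists), with a median of -1.69 below all matched random lists. Leaving out genes with shared spans, chosen after the data were seen, ended this call (Fisher's exact test, p = 0.179 adjusted over 21 lists). The called share stayed high, with 4 of 5 members (odds ratio 7.60) against 6 of 7 before (12.7). In the heat shock list 3 of 7 tested members fell, 1 rose and 3 were not called (two-sided Fisher's exact test, p = 0.291 adjusted over 21 lists, median -0.26 at percentile 25.5). HSP70-4 fell 2.82-fold to 30.9 FPKM from 87.2 FPKM, and HSFA2 fell 2.95-fold to 2.66 FPKM. HSP18.2 rose to 3.06 FPKM from 1.53 FPKM, a call lost when the adjustment included the untested genes (q = 0.0506 from the p-values of the authors' deposited table).

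Anthocyanin and glucosinolate genes leaned towards lower expression. The chalcone isomerase gene CHI fell 2.88-fold to 12.7 FPKM from 36.7 FPKM, the regulator PAP2 fell 4.68-fold to 2.86 FPKM from 13.4 FPKM, and the first enzyme gene of the pathway, CHS, fell 3.87-fold to 29.8 FPKM from 115 FPKM with a shared span. Of 11 tested anthocyanin and flavonoid genes 7 fell, none rose and 4 were not called (two-sided Fisher's exact test, p = 0.120 adjusted over 21 lists), with a median of -0.87 at percentile 0.11. Of 18 glucosinolate genes 8 fell, 2 rose and 8 were not called, and adjusted over the list alone 9 fell and 2 rose. CYP79F1, an enzyme gene of the aliphatic branch, fell 2.07-fold to 63.6 FPKM from 131 FPKM, and MYB51, a regulator of the indolic branch, fell 1.94-fold to 35.4 FPKM. CYP79B2 fell 1.94-fold, whereas its paralog CYP79B3 rose to 56.6 FPKM from 33.2 FPKM. The glucosinolate median was -0.29 at percentile 0.19, and the called share did not pass (two-sided Fisher's exact test, p = 0.120 adjusted over 21 lists).

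Photosynthesis genes rose almost as a group. The antenna gene LHCA3 rose 2.24-fold to 2265 FPKM from 1013 FPKM, LHCB3 rose 2.79-fold to 634 FPKM from 227 FPKM, LHCA4 rose 2.35-fold to 1623 FPKM from 692 FPKM, and LHCB1.1 rose 3.98-fold to 182 FPKM from 45.7 FPKM. LHCB3 and LHCA4 have shared spans, and members of the LHCB1, LHCB2 and RBCS families are near-identical copies whose single values are uncertain. All 14 light-harvesting genes in the list rose, by log2 0.71 to 1.99. The Rubisco small subunit genes RBCS1A (8061 and 9983 FPKM) and RBCS3B (5228 and 5584 FPKM) and the Rubisco activase gene RCA (1928 and 2109 FPKM) were not called. Of 22 tested members 19 rose, none fell and 3 were not called (86.4%, two-sided Fisher's exact test, p = 4.53e-06 adjusted over 21 lists), and the median of 0.75 lay above all matched random lists. Clock genes, which set the daily phase of these transcripts, were mixed. Of 14 tested 5 rose, 2 fell and 7 were not called, and adjusted over the list alone 6 rose and 2 fell (two-sided Fisher's exact test, p = 0.241 adjusted over 21 lists, median 0.26 at percentile 97.51). BOA rose 1.79-fold to 64.8 FPKM from 36.1 FPKM, PRR7 rose 1.56-fold to 32.5 FPKM, LNK2, with a shared span, rose 1.44-fold, and ELF4 fell 1.62-fold to 279 FPKM from 452 FPKM.

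Auxin genes leaned upwards, and the gibberellin and leaf polarity genes were mixed. GH3.3, which encodes an enzyme that conjugates auxin, rose 4.58-fold to 9.59 FPKM from 2.09 FPKM, and the auxin-response repressor IAA3 rose 3.15-fold to 64.2 FPKM from 20.4 FPKM. IAA2 rose 1.85-fold to 216 FPKM, and GH3.5 fell 1.78-fold to 17.1 FPKM. Of 17 tested auxin genes 6 rose, 3 fell and 8 were not called (two-sided Fisher's exact test, p = 0.171 adjusted over 21 lists, median 0.32 at percentile 99.3). GA20OX2, an enzyme gene of gibberellin synthesis, rose 5.71-fold to 6.37 FPKM from 1.12 FPKM, while the synthesis gene GA3OX1 fell 2.41-fold to 0.528 FPKM, the catabolic gene GA2OX6 fell 2.48-fold to 2.09 FPKM and the receptor gene GID1C fell to 16.8 FPKM from 24.0 FPKM. Of 11 tested gibberellin genes 3 rose, 3 fell and 5 were not called (two-sided Fisher's exact test, p = 0.196 adjusted over 21 lists, median 0.01 at percentile 68.8). YAB2, which promotes abaxial leaf identity, fell 2.79-fold to 4.48 FPKM from 12.5 FPKM, KAN2 of the same side fell 1.98-fold, and PHV of the adaxial side fell 1.68-fold, while PHB, also adaxial, rose 1.47-fold to 23.7 FPKM. Of 11 tested polarity genes 2 rose, 4 fell and 5 were not called (two-sided Fisher's exact test, p = 0.196 adjusted over 21 lists, median -0.32 at percentile 2.72).

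The series also asked about Polycomb, whose repressive complexes SWI/SNF remodellers can oppose, and transcripts of the list of Polycomb genes and antagonists changed little. The list was not chosen as genes marked by H3K27me3, and the H3K27me3 libraries were not analysed. Its values therefore do not show whether Polycomb acted differently on its targets in syd-5. CLF, which encodes an H3K27 methyltransferase, rose 1.41-fold to 7.96 FPKM from 5.66 FPKM, and ULT1 and ATX1, which oppose Polycomb, rose 1.55-fold to 6.74 FPKM and 1.33-fold to 4.21 FPKM. VRN1, which acts in vernalization, fell 1.31-fold to 21.6 FPKM, and the demethylase gene JMJ13 fell 1.40-fold to 4.68 FPKM. Of 23 tested members 3 rose, 2 fell and 18 were not called, and adjusted over the list alone 2 rose and 2 fell (two-sided Fisher's exact test, p = 0.436 adjusted over 21 lists, median -0.01 at percentile 66.8). The call of ATX1 was lost when the adjustment included the untested genes (q = 0.0771 from the p-values of the authors' deposited table). Of the 19 seed maturation genes in the list, 7 were tested, of which 1, the oleosin gene OLEO4, fell to 1.73 FPKM from 3.36 FPKM, and 6 were not called. The median of 1.64, at percentile 99.97, came from uncalled members such as OLEO2 (0.107 and 1.33 FPKM) and CRC (0.291 and 1.3 FPKM), and the called share did not pass the test (two-sided Fisher's exact test, p = 0.488 adjusted over 21 lists).

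Markers of single cell types and common reference genes served as a background. Of 11 tested root cell markers 3 rose, 2 fell and 6 were not called (two-sided Fisher's exact test, p = 0.428 adjusted over 21 lists, median 0.39 at percentile 99.0). CASP2, a gene of the root endodermis, rose to 3.53 FPKM from 0.946 FPKM, SHR rose to 8.79 FPKM from 6.49 FPKM, the phosphate transporter gene PHT1;1 fell to 11.2 FPKM from 24.3 FPKM, and the root hair oxidase gene RBOHC fell to 0.394 FPKM from 1.01 FPKM. Of 9 tested trichome and epidermis markers none rose, 2 fell and 7 were not called (two-sided Fisher's exact test, p = 0.728 adjusted over 21 lists, median -0.25 at percentile 24.7). The members that fell, CPC (to 1.12 from 5.33 FPKM) and ETC1 (to 0.356 from 2.59 FPKM), encode repressors of trichome fate. Of 9 tested reference genes 2 rose, 2 fell and 5 were not called (two-sided Fisher's exact test, p = 0.505 adjusted over 21 lists, median -0.02 at percentile 17.3). UBQ10 fell 1.44-fold to 533 FPKM and GAPC1 fell 1.44-fold to 127 FPKM. ACT2 rose 1.33-fold to 434 FPKM and EIF4A1 rose 1.29-fold to 205 FPKM, but these calls were lost when the adjustment included the untested genes (q = 0.0527 and 0.0746 from the p-values of the authors' deposited table). For lists with no separate count, the counts of risen and fallen genes adjusted over the list alone equal those over all tested genes.

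**Figure D3:**
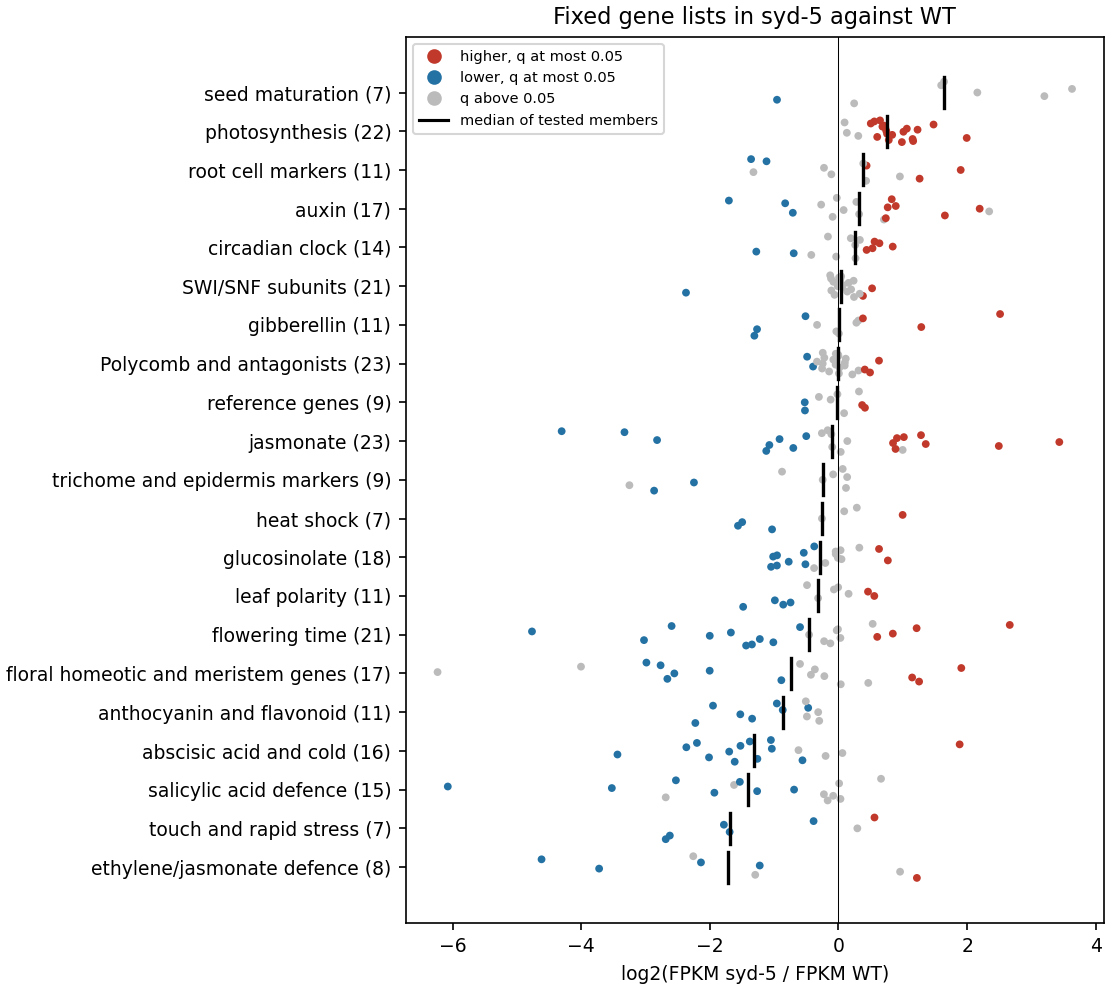
Log2 ratio of the authors' FPKM in syd-5 over WT (x axis) for the tested members of the 21 gene lists (rows, with the number of points), leaving out AP1 and PR1, which are listed at 0 in syd-5. Red points were called higher, blue points lower and grey points not called, and black bars give the median of the tested members, from 1.64 for seed maturation, where the 1 called gene is lower, to -1.72 for ethylene and jasmonate defence.

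The last comparison asked whether called genes gathered around the mutated locus. Within 5 Mb of SYD, 663 of 1933 tested genes were called (34.3%), against 31.9% elsewhere (odds ratio 1.12, two-sided Fisher's exact test, p = 0.0313). Within 2 Mb there was no such excess, with 238 of 729 genes called (odds ratio 1.03, two-sided Fisher's exact test, p = 0.747). By chromosome the called share ran from 31.2% on chromosome 3 to 33.8% on chromosome 2, and the smallest p was 0.172 adjusted over 5 chromosomes (Fisher's exact test). These tests treat genes as independent, although neighbouring genes tended to change together, so that their p-values may be too small. Of the nearest tested neighbours of SYD, CNGC15 (AT2G28260) fell to 2.94 FPKM from 4.98 FPKM, while LOG1 (AT2G28305) on the other side was at 46.5 and 46.2 FPKM and was not called.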

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

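Genes outside the authors' test held large values in syd-5, and the comparison of span lengths given here was chosen after these values were seen. They were singled out because they had at least 5 FPKM in syd-5 and were listed at 0 in WT or had at least 2-fold the WT value. AT2G12461 stood at 6941 FPKM in syd-5 and was listed at 0 in WT. AT5G27889 (48.4 FPKM), AT5G18661 (42.1), AT3G24516 (7.52), AT5G12450 (6.998) and AT3G28899 (5.91) were also listed at 0 in WT. AT3G04184 had 50.9 FPKM in syd-5 and 22.4 FPKM in WT.

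The same kind of value occurs in the other direction, as for AT4G05071, with 431 FPKM in WT and listed at 0 in syd-5. Of 23 untested genes with at least 5 FPKM in a genotype, 21 have a span of their own, from 135 to 213 bp, where the 5th percentile of tested genes is 704 bp. AT5G12450 is not among these, because its listed span of 6041 bp is shared with another gene. Transcripts shorter than the sequenced fragments, for which length correction inflates an FPKM from very few reads, are a candidate explanation for the 21 genes. For AT5G12450 it stays open, because a shared span does not give the gene's own length. The spans cannot test this explanation. If genes were left untested for few reads, those with at least 5 FPKM had to be short. In all, 4227 untested genes with spans of their own lay below that percentile. No biological explanation was tested, since 1 value per genotype cannot show whether a single library carries these reads.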

How the results depend on the processing

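No paired analysis was possible because the table gives 1 value per genotype and no libraries. For the same reason the planned fits with edgeR and DESeq2, another normalization, a pseudocount of 0.1, leaving out each replicate in turn, a replicate block (also in the set test) and other splits of the samples were not run, and whether 1 library decides any value cannot be seen. Depth is unknown, so the limit of detection is too.

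The total of 6380 called genes became 2298 (654 higher, 1644 lower) with at least a 2-fold difference, 1509 (432 and 1077) with at least a 2-fold difference on log2(FPKM + 1), and 3732 with a mean of at least 10 FPKM, where the lower genes numbered 1777. These are stricter rules, which remove calls by construction. At a threshold of 0.01 the total was 4498, with 1850 higher and 2648 lower. It was 6013 at a mean of at least 1 FPKM, 5664 with the adjustment over every gene with a p-value and 5758 without shared spans. Centring by -0.011 leaves the deposited calls, 6380, as they are. The filter on a mean of at least 10 FPKM, the log2(FPKM + 1) scale and the shared spans were chosen after the data were seen.

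The number of lists past the threshold, 5 as reported, was 9 with calls at 0.01 and 8 with calls of at least 2-fold. At 0.01 the salicylic acid (p = 0.0395 adjusted over 21 lists by Fisher's exact test), auxin (0.0262), anthocyanin (0.0499) and glucosinolate lists (0.0300) passed too. With at least 2-fold the floral (0.000466), ethylene and jasmonate (0.00358) and salicylic acid lists (0.00425) passed. The cause was not tested. Of 84 list alternatives 76 kept their side of the threshold. Without shared spans the touch list lost its call (0.179), with 4 of its 5 members still called (odds ratio 7.60). The position result ended at a 2 Mb window (p = 0.747, Fisher's exact test). Within 5 Mb at a threshold of 0.01 p was 0.0257, and within 10 Mb p was 0.0248 (Fisher's exact tests). The 10 Mb window held 2749 of the 3020 tested genes of chromosome 2. It nearly repeats the test of that chromosome (p = 0.172 adjusted over 5 chromosomes, Fisher's exact test). Such a window says little on gathering around SYD, and the cause was not tested. Of the 112 called genes among 113 named, 18 lost the call at 0.01, a stricter rule: ETC1, AT1G12570, GA3OX1, BRD1, AT1G55440, CLF, EIF4A1, ACT2, VRN1, OLEO4, UBQ10, SHR, DIP2, AT5G19800, AT5G22430, AT5G23155, JMJ13 and HSP18.2. EIF4A1, ACT2 and HSP18.2 also lost it with the adjustment over every gene, which tests more genes. None of 108 lost it at a mean of at least 1 FPKM, which tests fewer genes and so can hardly end a call. AP1, PR1, GA3OX1 and RBOHC lie below that mean and were not counted there. Among all 160 called list members the adjustment over every gene ended 13 calls: EIF4A1, ACT2, HSP18.2, ATX1, CUC3, SHP1, TFL1, MYB28, GA2OX1, EXPA18, PSBO1, TT7 and KO. SYD was at log2 -2.36 after centring.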

Other observations

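Gene families were grouped by the stem of their symbols, and these tests and the examples were chosen after the data were seen. The 121 families with at least 10 tested genes gave 242 one-sided Fisher's exact tests, 1 per direction, adjusted together. They count close copies as independent genes. Adjacent genes with the same symbol stem and spans of their own tended to change together (Spearman correlation 0.38 over 286 pairs). The adjusted p-values of the families may therefore be too small, and they describe these values only. Families with many lower members in syd-5 included enzymes, transporters and transcription factors. Of 143 genes with a CYP symbol 58 fell and 18 rose (adjusted p = 2.53e-08, Fisher's exact test). The stem is that of cytochrome P450 genes, but other genes that carry it were not removed. CYP707A3, an enzyme gene of abscisic acid breakdown, fell to 3.44 FPKM from 30.3 FPKM, and CYP707A2 to 0.328 FPKM from 3.68 FPKM. Glutathione transferase genes fell in 14 of 25 GSTU and 6 of 10 GSTF members and rose in none, with GSTU24 at 10.3 FPKM against 104 FPKM in WT and GSTU4 at 1.52 FPKM against 27.98 FPKM. The ABC transporters of the ABCC family fell in 11 of 13 members (1 rose), UGT glycosyltransferases in 23 of 48 (7 rose), BGLU glucosidases in 14 of 28 (3 rose), UMAMIT transporters in 13 of 32 (4 rose), LAC laccases in 7 of 12 (none rose) and SULTR sulfate transporters in 6 of 10 (1 rose). Transcription factor families with many lower members were MYB (33 of 79, with 6 higher), NAC (21 of 52, with 3 higher), WRKY (20 of 54, with 3 higher) and ERF (12 of 22, with 2 higher). WRKY53 fell to 5.65 FPKM from 79.5 FPKM and ERF5 to 24.6 FPKM from 119 FPKM, while MYB47 rose to 69.9 FPKM from 6.14 FPKM. Receptor kinases of the CRK family fell in 12 of 27 members and rose in 7.

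Families with many higher members were fewer. Of 20 genes with an RPL symbol, for proteins of the large ribosomal subunit, 16 rose and none fell (adjusted p = 1.61e-08, Fisher's exact test). The symbol covers plastid and cytosolic ribosomes. All 4 that the reference's synonyms place in plastids rose, with RPL4 at 411 FPKM in syd-5 and 265 FPKM in WT. So did 12 of the other 16, some of which also serve organelles, so that this is not a share for cytosolic ribosomes. RPL10B, RPL16A, RPL23AA and RPL23AB were not called. Of 22 genes with an RPS symbol, for the small subunit, 7 rose and 1 fell. This family did not pass (adjusted p = 0.213, Fisher's exact test). Of 14 PTAC genes, named for the plastid's transcription complex, 10 rose and none fell, with PTAC16 at 637 FPKM against 418 FPKM. The EMB and PDE genes, named for embryo and pigment defects of their mutants, rose in 40 of 107 and 7 of 14 members and fell in 3 and 1. Growth-related SAUR genes rose in 9 of 15 and fell in 1, with SAUR63 at 36.2 FPKM against 12.3 FPKM and SAUR28 at 8.52 FPKM against 1.65 FPKM. ATL genes rose in 6 of 12 (adjusted p = 0.0441, Fisher's exact test) and fell in 3.

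The rise of photosynthesis genes has technical and developmental candidate explanations, tested after the result was seen. A different scaling of the genotypes would move all genes alike, but the median of all tested genes was -0.0198 against 0.75 for the list. The sources do not say how the values were normalized, and a median near 0 can itself result from normalization. These medians therefore show only a rise relative to the typical tested gene, which a common factor cannot give. They do not show a rise in absolute amount. A larger share of leaf tissue in syd-5 would raise antenna and Rubisco transcripts alike. The median of the 14 light-harvesting genes exceeded that of the 5 Rubisco and activase genes by 0.69 (p = 0.00482, exact permutation over genes), and root cell markers, which a larger leaf share lowers, had a median of 0.39 at percentile 99.0 of matched lists. Both values go against this explanation, but it stays open because close copies leave only 2 Rubisco and activase families, root markers moved both ways (3 higher, 2 lower) and no replicate error is known. Harvest at another time of day cannot be told apart from an effect of the mutation either, because the median absolute change of the clock list, 0.43, lay at percentile 86.5 of matched lists, and the labels' protocols name no harvest time. A response to the loss of SYD stays open and untested.

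Neighbouring genes tended to change together, a hypothesis whose tests were chosen before their results were seen. Over 18602 adjacent tested pairs the log2 fold changes had a Spearman correlation across genes of 0.11, and 62.3% of the 2005 pairs with both genes called shared a direction, where 50.7% would by chance. That share was 77.1% of 83 such pairs with the same symbol stem, but only 55.8% of 389 with different stems and 55.4% of 1657 pairs 2 genes apart, all with spans of their own. Reads shared by overlapping genes could give this, but pairs with spans of their own gave a correlation of 0.115, above the highest of 1000 shuffles (0.0281). Tandem copies of a family add to it, with a correlation of 0.38 over 286 pairs of the same symbol stem. Pairs with different stems still gave 0.0606 against a highest shuffle of 0.0516, a narrow margin, and only 2572 of the 14003 pairs have names that allow this test, so that unnamed copies stay open. Genes are not independent replicates, and chromatin domains shared by neighbours remain an untested biological candidate.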
